A study of Mus musculus with 167 samples.

How the data were processed

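The series measured RNA in individually captured lymphoid-primed multipotent progenitors (LMPPs) from the bone marrow of female C57BL/6J mice at 4 and 14 months of age. Per the labels' protocols, marrow mononuclear cells were depleted of lineage-positive cells. LMPPs were then sorted as cells negative for lineage markers and CD150 and positive for Sca-1, c-Kit and CD34, with high Flt3. Cells were captured and their cDNA was amplified on a Fluidigm C1 microfluidic chip. The deposited table holds TPM values, which give transcript abundance scaled to the same total in each cell, for 38924 genes in 168 columns, 1 column per cell. Per the submitters' processing notes, Bowtie2 2.2.0, RSEM 1.2.12 and the mouse build mm10 were used to make it. Each column sums to 1000000, so sequencing depth is not kept and is unknown here. The number of genes detected stands in for it. The protocol mentions spike-in RNA, but no row of the table is a spike-in.

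The labels list 84 cells of 4 months and 83 of 14 months, while the table has 84 columns of each age. Column names show the age group but not which labelled cell a column is, so 1 of the 14-month columns has no label of its own and cannot be singled out. The 14-month columns carry 1 of 2 set numbers, 4 or 5, whose meaning is not given in the sources used here. The 4-month columns have no set number. Age therefore cannot be separated from capture. The 2 sets were treated as technical batches, and values for each are given beside the pooled value for some lists and genes. A pooled value given alone can still differ between the sets. No column of the table was left unused.

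Each labelled sample is 1 cell and no label names an animal, so each age counts as 1 sample. No p-value, standard error or count of changed genes was computed. A gene was called detected in a cell at TPM 1 or more. Cells with at least 1000 genes detected were kept, which left 66 of the 14-month and 64 of the 4-month columns. No filter was set on the mitochondrial share or on the share of a single gene. Mitochondrial transcripts reached 91.7% of TPM in a kept 14-month cell and 69.1% in a kept 4-month cell. In another kept 14-month cell the pseudogene Rpl15-ps3 had 563275 TPM. In such cells the fixed total lowers the values of the other genes. Columns of very high detection were kept and no doublet caller was run, since the protocol images the captured cells and a caller needs counts. A gene was measured when the mean of the 2 ages' shares of cells with it was at least 10%, which gave 9224 genes. For each gene the mean TPM, the mean and SD over cells of log2(TPM+1), with a pseudocount of 1, and the share of cells with its exact (Clopper-Pearson) 95% binomial interval were computed per age. Intervals cover counting error only. The difference is always 14 months minus 4 months on the log2(TPM+1) scale, which understates the change of low genes. The median difference of the measured genes was -0.36, and 77.0% of these genes had a negative difference. The differences given for genes are therefore relative to that median. The set differences are each relative to their own median, which was -0.43 for set 4 and -0.34 for set 5.

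For 28 gene lists, the median difference of the measured members was compared with 10000 random lists of the same size, matched on mean expression in 20 bins. It is given relative to the median of those lists, with its percentile among them, as a description of these libraries. Lists with fewer than 3 measured members got no percentile. Members of a list can vary together from cell to cell, which these random lists do not copy. As a yardstick chosen after seeing the data, the cells of each age were therefore split 50 times at random into equal parts, 100 splits in all, and the same relative median was taken between the parts. Each part holds fewer cells than an age, so their spread is wider than that of a comparison between the ages would be.

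The genes named are the 12 highest and 12 lowest differences among measured genes detected in at least 20% of cells of either age, leaving out predicted genes, mitochondrial transcripts and pseudogenes. To these were added the 2 highest and 2 lowest members of each list, and every member of a key panel and of the sort's marker genes. Some genes that these rules take, and 1 list whose median rests on such a gene, are not reported here. These rules, the lists and most alternatives were fixed before the data were examined. Gene symbols were found for 37607 of the 38924 gene identifiers, and 1317 had none. Coordinates and gene types are those of the GENCODE annotation of the same build. Shares of cells were also taken for 25% or more of the measured G2/M or S phase list, and for lymphoid and myeloid genes detected together. Cells were clustered with the Leiden method (resolution 1.0, 15 neighbours, 10 principal components, 1000 variable genes, cell cycle lists left out). Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and, for 1 alternative, scanpy 1.11.5 were used.

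The list and gene steps were tested on simulated data made from the 4-month cells, of which 32 of 64 were relabelled at random. All 6 lists changed 4-fold were found outside the central 95% of the random lists on the right side, and 200 of 200 changed genes had the right sign, among 9836 measured genes. The true log2 change of 2.00 came out as a median of 1.24 for raised and -1.13 for lowered genes. The simulated change multiplied values, so a gene absent from a cell stayed absent. A difference given here can also come from the share of cells with the gene, and can then exceed the change in mean TPM. Impact, for example, had means of 141 TPM at 14 months and 83.0 TPM at 4 months and a log2 difference of 2.15. Of 17 unchanged lists, 3 also lay outside. Before any change, 5 of 24 lists already lay outside it in that random split, among them the G2/M list at percentile 0.19. A percentile alone is thus not evidence of a difference between ages. Alternatives covered the pseudocount, the filters on genes and cells, the scaling of each cell, cells matched between ages on genes detected, the detection threshold, the G2/M threshold and the clustering settings.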

Results

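LMPPs are early blood progenitors that can give rise to lymphoid and to granulocyte-monocyte cells and have largely lost megakaryocyte and erythroid potential. The comparison asks how the transcripts of single LMPPs differ between mice of 14 and of 4 months. The table holds 84 columns of each age, and 45 of the 14-month columns belong to set 4 and 39 to set 5. Each age is 1 sample, with no replicate animals named, so the differences given here have no replicate check.

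Cells of 4 months had more genes detected than cells of 14 months. The median over all 84 columns was 3669.5 genes at 4 months (quartiles 1165 and 4463) and 2908 at 14 months (quartiles 1049.75 and 3876). It was 2403 in set 4 and 3284 in set 5. Counting genes at TPM above 0, the median was 4061.5 at 4 months and 3642.5 at 14 months. That count was 3170 in set 4 and 4248 in set 5, so over all columns set 5 then exceeded the 4-month cells. Fewer than 1000 genes at TPM 1 or more were found in 20 columns of 4 months, 16 of set 4 and 2 of set 5. These columns were left out of every comparison of expression. Among the kept cells the median was 3974.5 genes in 64 cells of 4 months, 3230 in 29 cells of set 4 and 3376 in 37 cells of set 5. Counting genes at TPM above 0 in these kept cells, it was 4526.5, 4097 and 4277, so the 4-month median was then the highest. Mitochondrial transcripts made up a median 12.4% of TPM at 4 months, 20.5% in set 4 and 15.8% in set 5. Small non-coding RNAs made up 2.56% at 4 months, against 0.943% in set 4 and 0.425% in set 5. Of the 8385 pairs of kept cells, 5 pairs, all of 14-month cells, had correlations across genes above 0.75, and the highest among the other pairs was 0.74, between 4-month cells.

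**Figure D1:**
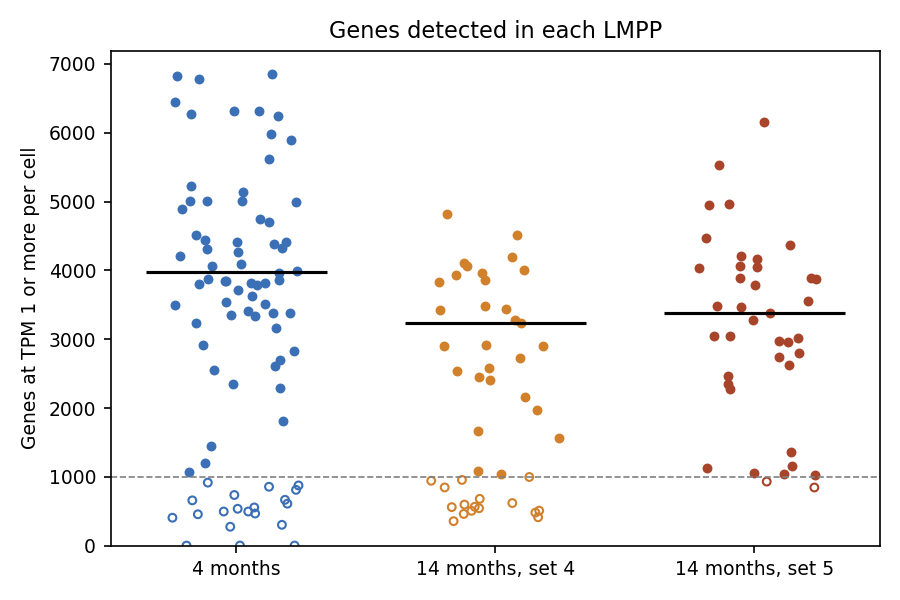
Number of genes at TPM 1 or more (vertical axis) in each column, for the 4-month cells and both sets of 14-month cells. Filled points are kept cells, open points are columns under the dashed line at 1000 genes, and bars are medians of the kept cells (3974.5, 3230 and 3376).

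The intervals of the shares of cells overlapped between the ages for each gene the sort selects for. Flt3, the cytokine receptor that defines the gate, was detected in 61 of 66 cells at 14 months (92.4%, interval 83.2 to 97.49%) and 64 of 64 at 4 months (interval 94.4 to 100%). Cd34 was detected in 87.9% and 89.1%, Kit in 53.0% and 67.2%, and Ly6a, which encodes Sca-1, in 37.9% and 39.1%. Over these 4 genes the relative median difference was -0.18, at percentile 33.0, with -0.47 in set 4 and 0.29 in set 5. Within it, Kit (-0.29) changed sign after quantile normalization and Flt3 (-0.13) in cells matched on genes detected. Kit and Flt3 were at -0.94 and -0.68 in set 4 and at 0.26 and 0.33 in set 5. Cd34 was at 0.12 in set 4 and -1.34 in set 5. Of the genes the sort selects against, Slamf1 (CD150), Cd3e and Ly6g were listed at 0 in every kept cell. A count of 0, taken as up to 3 cells, allows detection in up to 4.55% of cells at 14 months and 4.69% at 4 months and does not limit the share of cells that express a gene. Itgam, the myeloid integrin CD11b, was present at a low level. Its mean over all kept cells was 3.55 TPM at 14 months and 6.30 TPM at 4 months, and it was detected in 25.8% and 68.8% of cells. Its medians, 0.555 TPM and 1.72 TPM, lay on either side of the detection threshold, so these shares depend on that threshold. The relative difference of Itgam was -0.44, and -0.05 after quantile normalization.

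Immediate early genes, which cells switch on within minutes of a stimulus, were lower in the 14-month cells. All 18 measured members of the list of 19 had a lower mean log2(TPM+1) at 14 months, as did 77.0% of all measured genes. Of these members, 17 were also lower relative to the median gene. The list's relative median difference was -1.51, at percentile 0.00, with -1.32 in set 4 and -1.74 in set 5. In 100 random splits of the cells of 1 age into equal parts, the list never differed between the parts by more than 0.92. Btg2, an antiproliferative gene (chromosome 1, 134075170 to 134079120), had a mean log2(TPM+1) of 4.93 (SD over cells 3.63) at 14 months and 8.26 (SD 2.97) at 4 months, a relative difference of -2.97. Its shares of cells were 72.7% (interval 60.4 to 83.0%) and 93.8% (interval 84.8 to 98.3%). Atf3, a stress-induced transcription factor (chromosome 1, 191170296 to 191218039), was detected in 6 of 66 cells at 14 months (9.09%, interval 3.41 to 18.7%) and 39 of 64 at 4 months (60.9%, interval 47.9 to 72.9%). Ier3 was detected in 40.9% and 79.7% of cells. The AP-1 subunits Jun and Fosb had relative differences of -2.41 and -2.40, and the nuclear receptor Nr4a1 of -2.34. Klf4 differed less, at -0.63, and Egr2 was 0.30 above the median gene. These relative differences of Btg2, Atf3, Ier3, Jun, Fosb and Nr4a1 were negative in both sets. These 6 are among the lowest genes of the pooled difference, and both sets share the 4-month cells. Their signs in the sets are therefore no independent check, and 68.7% of all measured genes lay on the same side of the median in both. In cells matched on genes detected the list's relative median was -1.83.

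Other genes among the 12 lowest were Txnip, an inhibitor of thioredoxin (relative difference -2.72), Dusp6, a phosphatase of the ERK kinases (-2.41), and the chemokine gene Ccl4 (-2.74). Small non-coding RNAs made up the rest. Rn7sk had a mean TPM of 22.9 at 14 months and 2201 at 4 months, or 17.8 and 1094 without the highest cell of each age, and was detected in 30.3% and 64.1% of cells. Rn7s1 and Rn7s2, copies of the signal recognition particle RNA, had the same values, 8.63 and 83.5 TPM, because their reads cannot be told apart, and are uncertain as single genes.

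Genes of the G2/M phase were higher in the 14-month cells relative to matched genes, by a median of 0.73 at percentile 100. Of the 53 measured members, 36 had a higher mean at 14 months and 43 were above the median gene. The value was 0.49 in set 4 and 0.87 in set 5, and the sets differed from each other by 0.35 at percentile 99.91. With medians over cells in place of means the list was at 0.00 (percentile 61.4), and the other alternatives ran from 0.37 to 1.41. Members were detected in a mean 42.3% of 14-month and 42.4% of 4-month cells, so the median of many is near 0 in both ages. The median difference of all measured genes was also 0.0 in that setting, so it says little about this list. The median share of the list detected in a cell was 32.1% at 14 months and 33.0% at 4 months. Random equal parts of the cells of 1 age differed by up to 0.89, but they hold fewer cells than the ages, so this does not decide whether the choice of cells can give the difference. Ect2, needed for cytokinesis, had a relative difference of 1.47, and Cks1b, a partner of cyclin-dependent kinases, of 1.46 overall but -0.23 in set 4 and 2.83 in set 5. Top2a, the DNA topoisomerase of dividing cells, Mki67 and Cdk1 had relative differences of 1.03, 0.98 and 0.94. In that order they were 0.62, 0.22 and 0.74 in set 4 and 1.38, 1.60 and 1.12 in set 5. Hjurp and Tpx2 were the lowest members, at -0.79 and -0.49, but lay above the median gene in cells matched on genes detected. The share of cells with at least 25% of the list detected was 65.2% at 14 months (43 of 66, interval 52.4 to 76.5%) and 59.4% at 4 months (38 of 64, interval 46.4 to 71.5%), with 55.2% in set 4 and 73.0% in set 5. These intervals overlap. In cells matched on genes detected the shares were 81.4% and 46.5%, so the matching changes which cells are compared as well as their detection. The threshold is a point on a range rather than a class of cells, and 14 cells of each age lay within 5 points of it.

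In the cells past that threshold the median share of the S phase list detected was 53.5% at 14 months and 66.3% at 4 months, and their median number of genes detected was 3874 and 4725. The median over these cells of the mean log2(TPM+1) was 3.74 and 5.51 for the immediate early list, 3.68 and 4.46 for the early lymphoid list, and 2.08 and 2.41 for the granulocyte-monocyte list. The S phase list itself had a relative median of 0.22 at percentile 96.97, inside the central 95% of the random lists. It was 0.33 in set 4, beyond the central 95% (percentile 99.4), and 0.21 in set 5, inside it (percentile 94.5). The list lay beyond the central 95% in 10 of the 16 alternatives, with 0.76 in matched cells. Prim1, a DNA primase subunit, was its highest member at 1.58, Tipin was at 1.10, and Pcna, the DNA polymerase clamp, at 0.88. Atad2 was lower than the median gene, at -0.71. The share of cells with at least 25% of the S list was 72.7% (interval 60.4 to 83.0%) at 14 months and 84.4% (interval 73.1 to 92.2%) at 4 months. Among the 8 measured G1 cyclins and kinases the relative median was 0.03 at percentile 56.5. Cdk2 was detected in 16.7% of 14-month cells (interval 8.62 to 27.9%) and 57.8% of 4-month cells (interval 44.8 to 70.1%), and Cdk6 in 97.0% and 89.1%. Ccnd1 was at 0.39, and Ccnd3 at -0.41 with the opposite sign after quantile normalization and in matched cells. Quiescence genes and CDK inhibitors had a relative median of -0.11 at percentile 29.6, and it was 0.33 after quantile normalization.

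**Figure D2:**
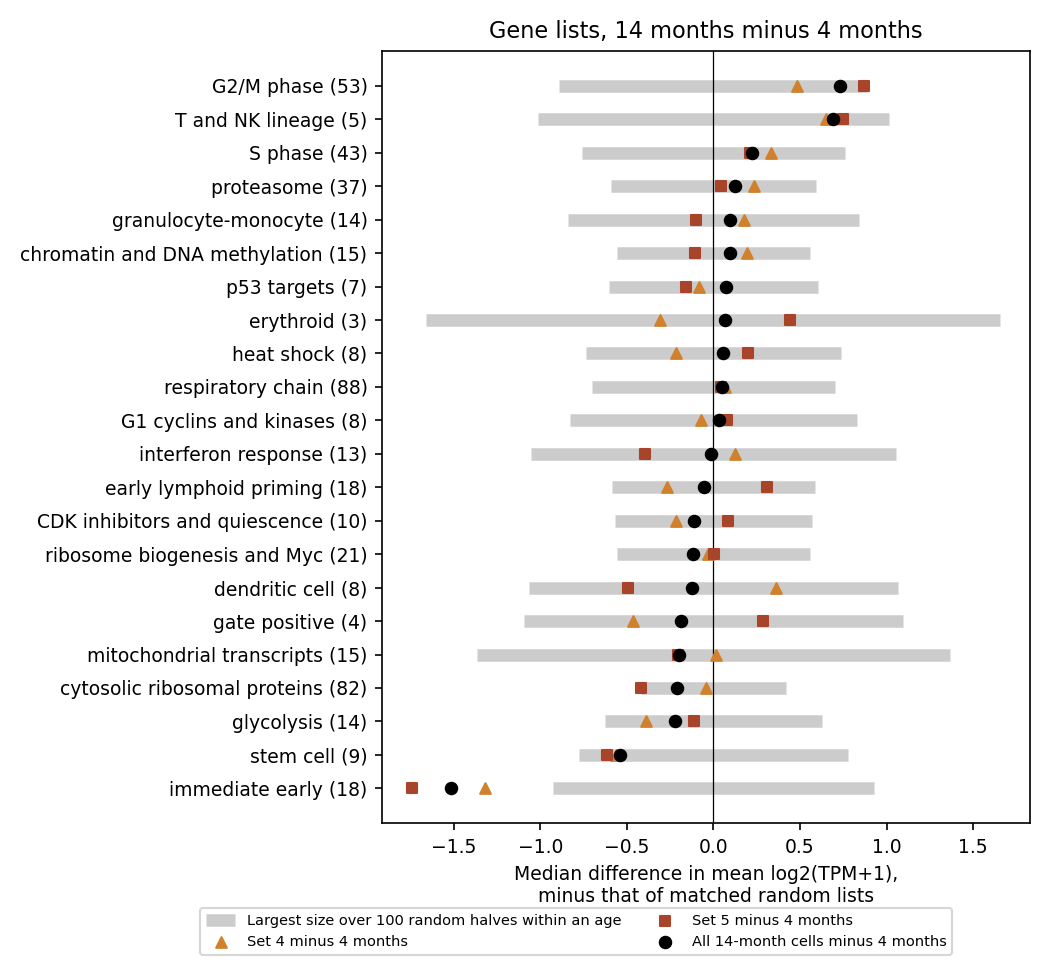
Relative median difference of the reported lists other than the key panel, each with at least 3 measured members (horizontal axis, log2(TPM+1) scale; number of measured genes in brackets). Black points are all 14-month cells, triangles and squares are sets 4 and 5, each against the 4-month cells, and grey bars reach to the largest difference, in either direction, between random equal parts of the cells of 1 age. The immediate early list (-1.51) is the only one outside its grey bar, and the G2/M list (0.73) lies within.

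The early lymphoid list did not stand apart from its random lists, and its members went both ways relative to the median gene. Of 18 measured members, 14 had a lower mean at 14 months, near the share of 77.0% over all measured genes, and 11 were below the median gene. Its relative median was -0.06 at percentile 37.7, and it had opposite signs in the sets, -0.27 in set 4 and 0.31 in set 5, so a difference is not excluded. It was also positive after quantile normalization and in matched cells. Dntt, which encodes terminal transferase (chromosome 19, 41029275 to 41059525), had a mean log2(TPM+1) of 7.34 (SD over cells 3.61) at 14 months and 6.10 (SD 4.26) at 4 months, a relative difference of 1.60, with 0.95 in set 4 and 2.14 in set 5. It was detected in 86.4% (interval 75.7 to 93.6%) and 75.0% (interval 62.6 to 85.0%) of cells. Il7r, the interleukin-7 receptor of lymphoid progenitors (chromosome 15, 9505788 to 9530176), was found in 13 of 66 cells (19.7%, interval 10.9 to 31.3%) and 5 of 64 (7.81%, interval 2.59 to 17.3%). Its share was 10.3% in set 4 and 27.0% in set 5. The lymphoid transcription factors Ikzf1 and Bcl11a were lower, at -1.01 and -0.91, in both sets. Notch1 was at -0.39 and Satb1 at 0.21. Rag1, Rag2 and Ccr9 were too rare to be measured, at 0.00%, 10.6% and 4.55% of 14-month cells and 6.25%, 6.25% and 7.81% of 4-month cells. For Dntt, Il7r and Ikzf1 the intervals of the shares overlap between ages.

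The granulocyte-monocyte list likewise did not stand apart, with a relative median of 0.10 at percentile 73.6 over 14 genes, 0.17 in set 4 and -0.10 in set 5, and it was negative after quantile normalization. Only with no filter on low values did it lie beyond the central 95%, at 0.22 and percentile 99.3. Its granule protease Ctsg (chromosome 14, 56099881 to 56102574) was detected in 31.8% of 14-month cells (interval 20.9 to 44.4%) and 14.1% of 4-month cells (interval 6.64 to 25.0%), a relative difference of 1.43. Elane, encoding neutrophil elastase (chromosome 10, 79886247 to 79888215), was detected in 16.7% and 6.25% of cells, and its share was 3.45% in set 4 and 27.0% in set 5. Its mean was 312 TPM at 14 months and 0.872 at 4 months, but without the 2 highest cells the 14-month mean was 7.92. Mpo, myeloperoxidase, was detected in 62.1% and 54.7% of cells with a relative difference of 0.36. That difference had opposite signs in the sets, -0.26 in set 4 and 0.89 in set 5, with shares of 55.2% and 67.6%. Csf1r, the M-CSF receptor, was detected in 6.06% (interval 1.68 to 14.8%) against 26.6% (interval 16.3 to 39.1%), and Csf3r, the G-CSF receptor, in 34.8% (interval 23.5 to 47.6%) against 71.9% (interval 59.2 to 82.4%). The mean of Csf3r was nevertheless higher at 14 months, 52.6 TPM against 38.4 TPM. Its relative difference had opposite signs in the sets, 0.08 in set 4 and -1.08 in set 5. The transcription factors Irf8 and Cebpa had relative differences of -0.64 and -0.16.

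Most kept cells had lymphoid and myeloid genes together. At least 1 of Il7r, Dntt, Rag1, Rag2 and Ccr9 was found with at least 1 of Mpo, Elane, Prtn3, Ctsg and Csf1r in 77.3% of 14-month cells (51 of 66, interval 65.3 to 86.7%) and 70.3% of 4-month cells (45 of 64, interval 57.6 to 81.1%). Independence of the 2 groups of genes within an age would give 77.2% and 70.8%. The share was 82.8% in set 4 and 73.0% in set 5. A lymphoid gene was found in 89.4% and 78.1% of cells, a myeloid gene in 86.4% and 90.6%, and neither in 1 cell of each age. The lymphoid gene was mostly Dntt (86.4% and 75.0% of cells), and the myeloid gene mostly Prtn3 (75.8% and 78.1%) or Mpo (62.1% and 54.7%). The intervals overlap between ages for each of these shares.

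Stem cell genes were lower in the 14-month cells relative to matched genes, with a median of -0.54 at percentile 0.72, -0.56 in set 4 and -0.61 in set 5. All 9 measured members of the list of 20 had a lower mean at 14 months, as did 77.0% of all measured genes. Of these members, 7 were below the median gene. The list lay beyond the central 95% of the random lists in 11 of the 16 alternatives, but inside it with pseudocount 10 (-0.21), no filter on low values (-0.12), genes in at least 30% of cells (-0.37), even-numbered cells only (-0.17) and medians over cells (-0.31). Random equal parts of the cells of 1 age, which hold fewer cells than the ages, differed by up to 0.78, so the choice of cells stays open. Hlf, a stem cell transcription factor (chromosome 11, 90336536 to 90390895), was detected in 43.9% of 14-month cells (interval 31.7 to 56.7%) and 70.3% of 4-month cells (interval 57.6 to 81.1%), a relative difference of -1.18. Mecom, which encodes the zinc finger factor Evi1, was detected in 22.7% (interval 13.3 to 34.7%) and 53.1% (interval 40.2 to 65.7%). Gata2 was detected in 12.1% and 29.7% of cells. Mllt3 was above the median gene at 0.24 and Ly6a at 0.32. Fewer genes were detected in the 14-month cells. In cells of both ages matched on that number the list's relative median was -0.92. The matching also changes the shares of cells past the G2/M threshold, as given above. The median over cells of the stem cell list's mean log2(TPM+1) differed across that threshold. It was 2.746 past and 2.267 under it at 4 months, and 1.417 and 1.575 at 14 months. The matched value therefore does not decide whether detection contributes.

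**Figure D3:**
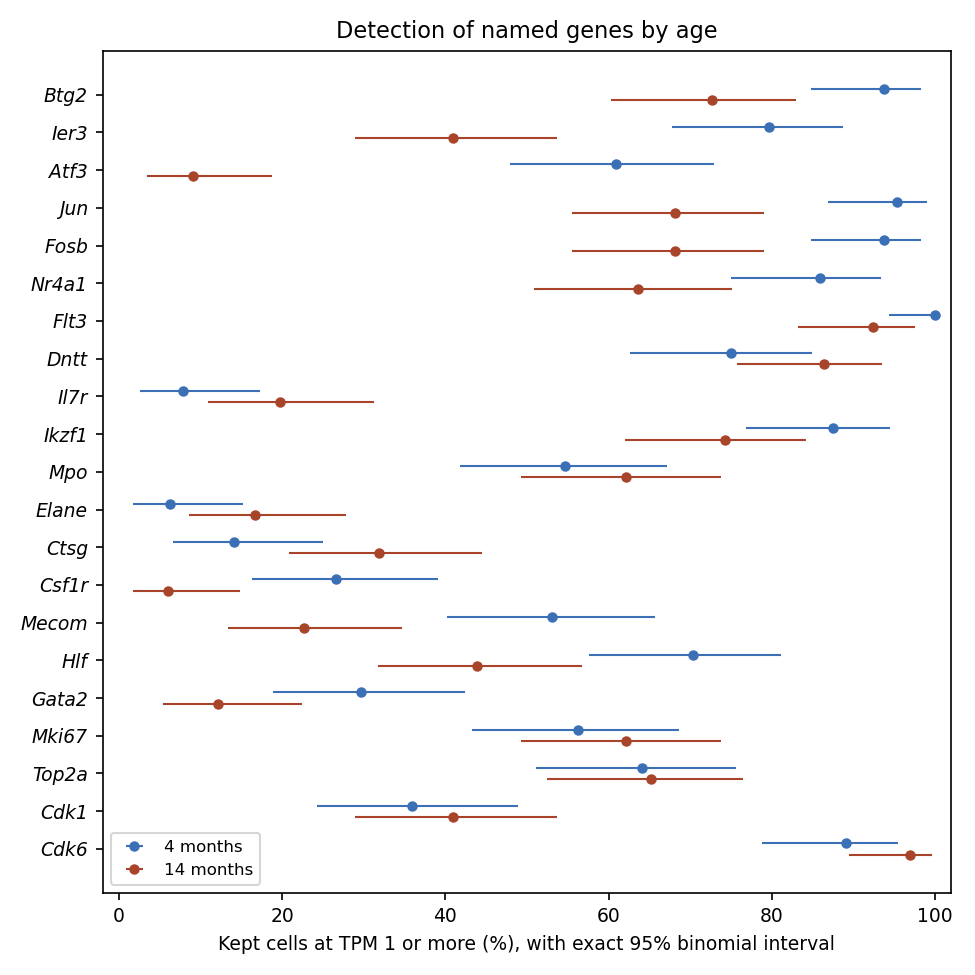
Share of kept cells with TPM 1 or more (horizontal axis, percent) for named genes at 4 months (blue, 64 cells) and 14 months (red, 66 cells). Lines are exact 95% binomial intervals, which cover counting error only, and those of Atf3 (9.09% and 60.9%) and Mecom (22.7% and 53.1%) do not overlap.

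Among the genes of the megakaryocyte lineage, Cd9, a tetraspanin, had a relative difference of -1.35. Vwf was present at a mean of only 1.92 and 7.57 TPM. Of the erythroid list 3 genes were measured, at a relative median of 0.07 and percentile 58.5 (-0.31 in set 4, 0.44 in set 5, and negative after quantile normalization and in matched cells), with Tfrc, the transferrin receptor, at 1.37. Gata1 was listed at 0 in all kept cells, and Itga2b and Procr were detected in 1 cell each at 14 months and in 4 and 3 cells at 4 months. The T and NK list had 5 measured genes and a relative median of 0.69 at percentile 98.8, 0.65 in set 4 and 0.75 in set 5, but it lay inside the central 95% after quantile normalization (0.58, percentile 96.3) and in matched cells (0.42, percentile 84.4). Random equal parts of 1 age differed by up to 1.01. Its highest member was Nkg7, a granule membrane protein gene, at 2.07. Of the B lineage list only Ighm (0.13) and Cd79b (-0.76) were measured, and of the stroma and endothelium list only Emcn (-0.57) and Lepr (-0.33). No member of the basophil, mast and eosinophil list was measured. The dendritic cell list had a relative median of -0.12 at percentile 32.0, 0.36 in set 4 and -0.49 in set 5, with the MHC class II chaperone gene Cd74 at -0.85.

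The genes highest in the 14-month cells relative to the median gene were Rps12 (2.86), Impact (2.51), H2afz (2.27) and Rps27 (2.19). They were followed by Tram1, Fkbp3, Sdhd, Cenpk, Nkg7, Tmem167, Cycs and Tra2b, the last at 1.92. Impact, a regulator of translation, was detected in 75.8% of 14-month cells (interval 63.6 to 85.5%) and 48.4% of 4-month cells (interval 35.8 to 61.3%). H2afz, the histone variant H2A.Z, had a mean of 4596 TPM and 1427 TPM. Cenpk, a kinetochore gene, was detected in 54.5% and 29.7% of cells. Rps12 and Rps27 have near-identical processed copies in the genome, so their values depend on how reads were divided and are uncertain. All of these genes had positive relative differences in both sets. They were picked on the pooled difference, and both sets are compared with the same 4-month cells, so this is no independent check. Of all measured genes, 68.7% lay on the same side of the median in both sets.

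The cytosolic ribosomal protein genes had a relative median of -0.21 at percentile 1.52 over 82 genes, of which 50 were below the median gene. The value was -0.04 (percentile 33.8) in set 4 and -0.42 in set 5, and the sets differed from each other by -0.38 at percentile 0.20, more than the ages did in all kept cells. In matched cells the list was at -0.45 (percentile 0.00). Random equal parts of the cells of 1 age differed by up to 0.42 in this list. Rplp1 was the lowest at -1.05. The list of mitochondrial transcripts had a relative median of -0.20 at percentile 19.2 over 15 genes that went both ways, from mt-Nd3 at -2.48 to mt-Co3 at 1.26, and lay beyond the central 95% in matched cells (-0.70, percentile 0.495). Nuclear genes of the respiratory chain had a relative median of 0.05 at percentile 71.5 over 88 genes, with Cycs, cytochrome c, at 1.97 and Cox7c at -1.33. The proteasome list was at 0.12 and percentile 81.0, with Psma3 at 1.79 and Psmb7 at -1.78. In matched cells these 2 lists lay beyond the central 95%, the respiratory chain at 0.53 (percentile 99.98) and the proteasome at 0.52 (percentile 99.3). The ribosome biogenesis and Myc list was at -0.12 and percentile 22.6. Its members Npm1 and Dkc1 were at 1.46 and 1.46, Nop56 at -1.50 and Odc1, ornithine decarboxylase, at -1.31. Myc itself was at 0.39.

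The lists of chromatin, glycolysis, p53, heat shock and interferon genes lay inside the central 95% of the random lists, and in cells matched on genes detected all but the interferon list changed sign, while that list moved to -0.35 (percentile 5.81). Chromatin and DNA methylation genes were at 0.09 (percentile 67.1), although Hdac1 was at -1.68 and the methyltransferase gene Dnmt3a, at -0.95, was detected in 40.9% of 14-month cells and 68.8% of 4-month cells. Glycolysis genes were at -0.22 (percentile 14.5), p53 targets at 0.07 (percentile 62.9, but -0.08 in set 4 and -0.16 in set 5) and heat shock genes at 0.05 (percentile 58.3). Interferon response genes were at -0.01 (percentile 47.4), with 0.13 in set 4 and -0.40 in set 5, and Oasl2 was the lowest at -1.24. In set 5 alone this list was beyond the central 95% (percentile 2.37), and the sets differed from each other by -0.75 at percentile 0.005. The key panel of 26 genes, which overlaps the other lists, was at 0.30 and percentile 97.51, just beyond the central 95%. It had opposite signs in the sets, -0.14 in set 4 and 0.45 in set 5, and random equal parts of the cells of 1 age differed by up to 0.46.

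Clustering gave 5 groups of cells, none of which had a marker from the fixed cell type lists among its 10 leading genes, so they stay numbered. Their median numbers of genes detected ran from 1403 in cluster 4 to 6260 in cluster 5. Cluster 1, led by the replication and mitosis genes Rfc4, Pbk and Top2a, held 40 cells with a median 68.9% of the G2/M list and 59.3% of the S list detected. Cluster 5, with 14 cells, had more of both, 75.5% and 82.6%. Cluster 2 held 35 cells with 20.8% of that list. Because the leading genes also differ between the ages, cluster sizes were not compared between them.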

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

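The results here come from the columns left out for having fewer than 1000 genes detected, which no comparison above uses. Each is a single gene, leaving out mitochondrial transcripts, predicted genes and pseudogenes, that took at least 100000 TPM in such a column and exceeded its level in every kept cell. In set 4, number 10 had 499678 TPM of Camp, a neutrophil granule gene, against a highest value of 364930 in the kept cells, and number 23 had 858896 TPM of Hsp90ab1, against 4650. In set 5, number 63 had 142145 TPM of Dad1 and 190727 of Imp4. Among the 4-month columns, number 10 had 653369 TPM of Slc25a5 and 346631 of Ric8a, the only 2 genes detected in it. Number 25 had 164225 TPM of Cdk11b, number 42 had 1000000 of Syncrip, its only gene, and number 48 had 953436 of Mrpl22. No explanation was tested for the values in the other columns.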

How the results depend on the processing

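Values are relative medians of lists unless named otherwise, and none has a test. No paired analysis was possible because the labels pair no cell of 1 age with a cell of the other. The planned split into odd and even numbers of the titles was not run, because the numbers in the column names could not be matched to those in the cell titles. The number in the column name was used in its place, and this split, the separate sets, the columns correlated above 0.75 and the leaving out of each cell were chosen after seeing the data. The immediate early list stayed negative and beyond the random lists in all 16 alternatives (-2.42 to -0.86), and the stem cell list stayed negative in 16 and beyond them in 11. The G2/M list stayed positive and beyond them in 15. The S phase list stayed positive in 15 and was beyond them in 10, though not in the main analysis. The early lymphoid and granulocyte-monocyte lists had the main sign in 11 of 16 each, and the granulocyte-monocyte list was beyond the random lists in 1, with no filter on low values (0.22). None of the 24 highest and lowest genes changed sign, but they were picked as the extremes of the same data, so this is a weak check. Leaving out each of the 66 kept 14-month cells in turn gave -1.58 to -1.47 for the immediate early and 0.66 to 0.79 for the G2/M list. The cause was not tested for any value below, and unknown depth limits every share.

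Pseudocount 0.1 gave -0.90 for stem cell, 1.08 for G2/M, 0.52 for S phase and -2.31 for immediate early genes. Pseudocount 10 gave -0.21 for stem cell, 0.37 for G2/M and -0.86 for immediate early genes. With no filter on low values, stem cell genes were at -0.12 and immediate early genes at -1.23. With genes in at least 30% of cells, granulocyte-monocyte genes were at -0.23, G2/M at 0.85 and immediate early at -1.77. With no filter on cells G2/M was at 0.61, with a stricter filter on cells S phase was at 0.36, and without cells of high detection G2/M was at 0.89. In cells matched on genes detected, stem cell was at -0.92, G2/M at 1.41, S phase at 0.76 and immediate early at -1.83. Odd numbers gave -0.87 for stem cell and 0.96 for G2/M, and even numbers -0.17, 0.47 and, for S phase, 0.035. Set 4 alone gave -0.27 for early lymphoid, 0.50 for G2/M and -1.31 for immediate early genes. Set 5 alone gave 0.31 for early lymphoid, -0.11 for granulocyte-monocyte, 0.87 for G2/M and -1.74 for immediate early genes. Quantile normalization gave -1.18 for immediate early genes. Medians over cells gave 0.00 for G2/M, 0.00 for S phase and -2.42 for immediate early genes. The G2/M and S phase values say little, since the median of many members of these lists is near 0.00 in both ages.

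The share of cells past the G2/M threshold at 14 and 4 months was 81.8% and 78.1% with detection at TPM above 0, 51.2% and 45.2% with no filter on cells, 86.4% and 95.3% with 15% of the list, and 43.9% and 39.1% with 40%. At 14 months it was 51.5% with TPM 10 or more and 81.4% in matched cells. Lymphoid and myeloid genes together were in 63.6% of 14-month cells at TPM 10 or more, 88.4% of them in matched cells, and 53.6% of 4-month cells with no filter on cells. The number of clusters, 5, was 4 to 7 in the 6 alternatives set beforehand and 6 with the neighbour graph of scanpy, tried after seeing the data.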

Other observations

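A few kept cells had high values of some myeloid genes, and these cells and genes were singled out after their values were seen. In set 5 the cell numbered 85, with 4064 genes detected, had 13815 TPM of Elane, 13569 of Mpo, 3906 of Ctsg and 1992 of Ms4a3, genes of granulocyte-monocyte progenitors. The cell numbered 77 of the same set, with 1041 genes detected, had 6299 TPM of Elane and 6607 of Mpo. Among the 4-month cells the highest Mpo value was 5902 TPM and the highest Elane value 26.8 TPM. Values of 1000 TPM or more were in 8 cells of 14 months and 3 of 4 months for Prtn3, 7 and 3 for Lyz2, 3 and 1 for Ctsg, 2 and 0 for Elane, 1 and 0 for Ms4a3 and for Ccr2, 6 and 7 for Mpo and 0 and 1 for Spi1. The highest values of Spi1 (2027 TPM), S100a8 (524 TPM) and S100a9 (974 TPM) were in 4-month cells. Ly6c2, a surface antigen of monocytes, was listed at 0 in every 4-month cell and was detected in 8 of 66 cells at 14 months, where it reached 6592 TPM in set 5 and 4846 TPM in set 4. The same 2 cells had the highest Lyz2 values, 5026 and 4767 TPM. Camp, a neutrophil granule gene outside the fixed lists, made up 364930 TPM of 1 kept cell of set 5 with 1021 genes detected.

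The tests of capture or handling, of which cells were captured and of the choice of cells were chosen after the result was seen. For the immediate early genes, at -1.51 in the 14-month cells, fewer genes detected is argued against by the 43 cells of each age matched on that number, where the list stood at -1.83. Transcript length and GC content are argued against as the whole cause by random lists matched on both as well as on expression, against which the list stood at -1.35. Random equal parts of the cells of 1 age differed by at most 0.92. A batch of capture or handling and age cannot be told apart, because each set holds 1 age: the 2 sets of 14-month cells differed from each other by only -0.21, but neither set holds 4-month cells. The small non-coding RNAs, which were also lower in both 14-month sets, may come from such a batch, and a biological effect of age stays open and untested.

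For the G2/M genes, higher by 0.73, similar columns, correlated above 0.75, are argued against by the value of 0.73 without 1 column of each pair. Fewer genes detected stays open, since the matched cells, where the list stood at 1.41, cannot decide it. Matching moved the share of 14-month cells past the G2/M threshold from 65.2% to 81.4%, so the bound written beforehand for this test was wrong, while the immediate early list differed little across that threshold (3.74 past and 3.53 under it in 14-month cells). The choice of cells stays open, since random equal parts of 1 age, smaller than the ages themselves, differed by up to 0.89, and so does which cells were captured, since the 2 sets of 1 age differed by 0.35. Whether age itself could account for any of it was not tested.

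Among the 8385 pairs of kept cells the median correlation across genes was 0.51, and 5 pairs, all of 14-month cells, exceeded 0.75. The closest, number 76 of set 4 and number 94 of set 5, reached 0.97, with a median absolute log2 ratio of 0.33, against 0.60 to 2.08 in the other 4 pairs. A candidate explanation is library material shared between columns. Of the 1356 genes found in exactly 2 of the 168 columns, the closest pair held 11. Pairs outside the 5 held at most 9, with a median of 0. A number above that of any other pair was predicted beforehand for shared material, and this was met, but the gap is too small to decide. Without counts the sampling noise between columns is unknown, and a biological explanation, such as closely related cells, was not tested.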
